A study of Homo sapiens with 6 samples.

How the data were processed

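Small RNA was sequenced from extracellular vesicles (EVs) of MCF-7, a luminal human breast cancer cell line, after treatment with Ac4ManNAz, an acetylated mannosamine carrying an azide that cells convert into azide-bearing sialic acid. RNA was extracted with TRIzol and made into libraries with the VAHTS small RNA kit, per the labels' protocols. The 6 libraries form 2 groups of 3, which the labels number 1 to 3 in each group. Input libraries hold bulk EV RNA and enriched libraries hold the fraction recovered through the Ac4ManNAz label. The chemistry of that recovery is not given in the sources used here. A recovery from EVs without the label was not analysed here.

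The deposited table holds raw read counts, whole numbers that the authors did not normalise, for 1652 rows and 6 libraries. Bowtie2 2.5.1 and the build GRCh38.p14 are named in the submitters' processing notes. The counting tool, the annotation release, adapter trimming, the handling of reads that fit several places and the use of molecular identifiers are not given in the sources used here. Of the rows, 934 are mature miRNAs and 718 are Ensembl genes. GENCODE release 29, an annotation of GRCh38, named 717 of these genes: 434 snoRNA, 268 snRNA and 15 rRNA genes, with 1 gene left unmatched. Of these genes, 162 have only the name of an Rfam family. Coordinates and host genes come from the same annotation. A miRNA's position is that of its precursor, and exons were taken from basic transcripts without retained introns. The lists fixed for tRNA, mitochondrial tRNA, Y RNA, vault RNA, 7SL RNA, piRNA and tRNA isotypes had 0 members among these rows and were not analysed here.

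The counting affects what a row means. 46 rows in 21 sets with at least 50 reads held the same counts in all 6 libraries, so reads of 1 RNA were counted at each copy of its gene. Levels of single copies of U1, U2, U4, U5, U6 and U3 genes, and of miRNAs with identical mature sequences, are therefore uncertain, and a class share counts some reads more than once.

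Total counts were 7567157, 7750003 and 7523611 for input libraries 1 to 3, and 335849, 326501 and 509798 for enriched libraries 1 to 3. The mean input total was 19.5 times the mean enriched total, so an RNA at 0 reads in the enriched group is less tightly bounded than one at 0 in the input group. A group at 0 was given a floor of 3 reads over the group. Floors and counting intervals, at 95% confidence by the exact binomial method, cover counting error only, because reads may be PCR copies of 1 molecule. Ratios built on them use the TMM factors given below. A bound from a floor holds on that scale only and moves with the scaling.

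Replicates of a group were compared by a chi-square test of their counts over rows with at least 10 reads. The chi-square per degree of freedom lay between 1.24 and 5.85 over the 6 pairs. Every pair differed by more than sampling noise, so the 3 libraries of a group were not merged. Pairs with replicate 3 stood apart. In 36 rows both replicate 3 libraries had 0 reads although the other libraries together had at least 10, and with these rows left out the ratio lay between 1.22 and 1.68. These last ratios lie close to sampling noise, and the labels do not say that replicates came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical, and not a spread between preparations.

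Input and enriched libraries were compared with edgeR 4.0.16 in R 4.3.3. RNAs were kept by filterByExpr (953 of 1652), libraries were scaled by TMM factors, and the quasi-likelihood test was fitted by group alone to all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are enriched minus input, with a standard error taken as the size of the change over the square root of the F statistic. CPM values are read counts scaled by library size and TMM factor, so their SD includes differences in the factors, which were 0.664, 0.673 and 0.729 for the input libraries and 1.44, 1.45 and 1.46 for the enriched ones. Shares of all reads do not depend on these factors. Shares and numbers of detected RNAs were compared by exact two-sided permutation tests that exchange libraries freely, whose smallest possible p with 3 against 3 is 0.1. With signs flipped within same-numbered pairs, a test added after seeing the data, the smallest possible p is 0.25. Classes and miRNA lists, set by name patterns, were tested with camera (limma 3.58.1, preset correlation 0.01), repeated with an estimated correlation, and with fry, over the 16 lists with at least 3 tested members. Fry's directional and mixed tests do not compare a list with other RNAs.

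Design, lists, alternatives and the rule for named RNAs were fixed before the data were examined. The rule took the 10 largest changes in each direction among RNAs past the threshold with at least 10 reads per library on average in the higher group and no overlap between groups, the 10 RNAs with the highest CPM, and the 2 most abundant members of each list, with the 2 most changed members of each list past its threshold. It gave 69 RNAs. RNAs outside it are marked where they appear. Alternatives were DESeq2 size factors, total counts or upper-quartile factors in place of TMM, no or a stricter low-count filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were the 36 rows left out, both replicate 3 libraries left out, all libraries thinned to 326501 reads before the edgeR and list tests (planned for the number of detected RNAs), rows with the same counts kept once, miRNA lists tested against other miRNAs only, and miR-21-5p left out of the totals.

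Whether replicate numbers pair the libraries was checked by correlating deviations from the group means over the tested RNAs. Same-numbered libraries correlated at 0.30, 0.26 and 0.66, all over 0.1, the limit above which the numbers were treated as pairing the libraries. The edgeR fit and the permutation tests reported as results are unpaired, and the pairing enters only as the block and the sign flips. The labels state no shared origin, and libraries 1 and 2 correlated as well across numbers (0.29 and 0.35). Without the 13 tested rows among the 36, the same-number values were -0.02, -0.02 and 0.03. The correlations thus rest on those rows, and the counts show no pairing beyond them.

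The test was tried on counts simulated at the real library sizes with known changes. 873 simulated RNAs passed the low-count filter. It called 67.4% of RNAs raised 2-fold and 59.6% of those lowered 2-fold, 98.0% of those raised 4-fold and 89.1% of those lowered 4-fold. Of its calls, 5.70% were false. In the simulation 684 of the 873 RNAs were unchanged, and rises and falls were balanced. In the real data 846 of 953 RNAs changed and the direction followed the class, so these rates may not hold there.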

Results

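Small RNA of EVs from MCF-7 cells was sequenced in 3 libraries of bulk EV RNA (input) and 3 libraries of the fraction recovered through an Ac4ManNAz label (enriched). The comparison asks which small RNAs of these vesicles were over- or under-represented in the labelled fraction, the fraction in which RNAs bearing sialic acid glycans (glycoRNAs) are sought. Input libraries held 7523611 to 7750003 counted reads and enriched libraries 326501 to 509798. Reads were counted for mature miRNAs, for snoRNAs, which guide modification of other RNAs, for snRNAs, which mostly build the spliceosome, and for a few rRNA genes. Background carried through the recovery has no measured value here, because EVs without the label were not analysed.

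The labelled fraction had a different make-up from bulk EV RNA. miRNAs took 86.9% ± 0.0161 of input reads and 31.7% ± 0.109 of enriched reads (SD, n = 3 libraries per group here and below). The share of rRNA went from 10.3% ± 0.00827 to 42.8% ± 0.0526, and nearly all of it was 5.8S rRNA, a component of the large ribosomal subunit. snoRNAs made up 2.12% ± 0.0254 of input and 14.2% ± 0.306 of enriched reads, which is 6.70 times the input share. snRNAs made up 0.606% ± 0.00270 and 11.3% ± 0.152, which is 18.6 times the input share. In each of these classes the 3 enriched libraries lay on one side of the 3 input libraries, and the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. With the most abundant row, the 5.8S gene RNA5-8SN2, left out of the totals, the rRNA difference shrank from 32.4 to 0.0452 percentage points, while the snoRNA and snRNA differences grew from 12.1 to 22.5 and from 10.7 to 19 points.

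**Figure D1:**
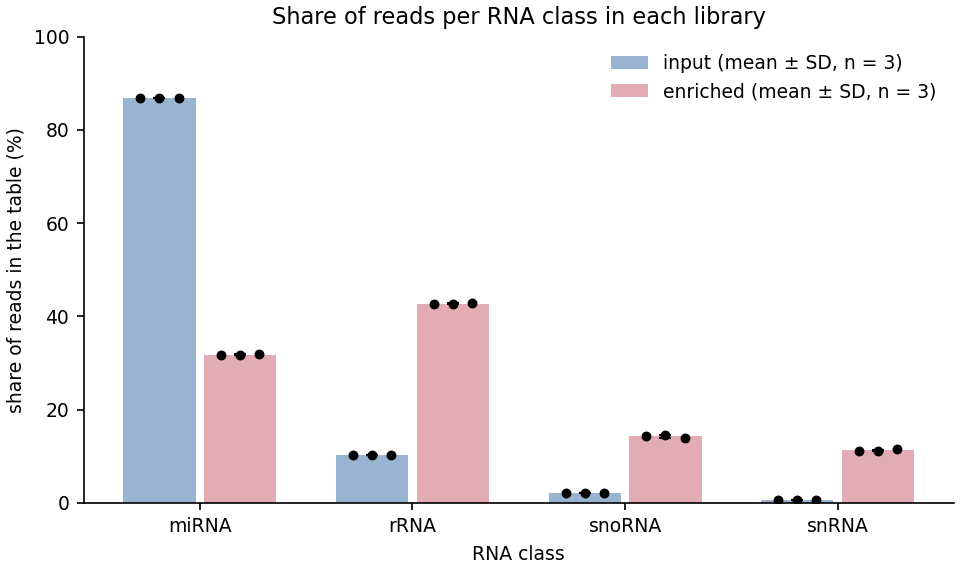
Share of counted reads (%, y axis from 0) taken by each RNA class in input and enriched libraries; bars are group means, error bars the SD of 3 libraries, and black points single libraries. miRNA fell from 86.9% to 31.7% of reads, and rRNA, snoRNA and snRNA took larger shares of the enriched libraries.

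Within these classes, rows of U2 snRNA, the spliceosomal RNA that pairs with the intron branch point, went from 0.408% ± 0.00244 to 9.42% ± 0.126 of reads, 23.1 times the input share. The U2 rows rose by 9.02 percentage points and all snRNA rows by 10.67, so U2 made up most of the snRNA rise. Many U2 reads were probably counted at more than 1 gene copy. RNU2-2P and RNU2-36P held 46369 and 45157 input reads and 54826 and 42481 enriched reads, most of the U2 reads. The U2 and snRNA shares and their rise in points may therefore be too high. Rows of U3 (SNORD3), which acts in early processing of ribosomal RNA, went from 1.48% ± 0.0162 to 4.69% ± 0.0706. H/ACA snoRNAs, guides of pseudouridylation, went from 0.0561% ± 0.000952 to 1.28% ± 0.00490, and C/D snoRNAs, guides of ribose methylation, from 2.03% ± 0.0191 to 12.4% ± 0.0636. miR-21-5p, an oncogenic miRNA and the most abundant miRNA of the input, went from 22.6% ± 0.0270 to 3.96% ± 0.0262. All 5 differences had an exact permutation p of 0.1.

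Of the 1652 rows, input libraries had 1359 ± 45.0 with at least 1 read and enriched libraries 934 ± 10.8 (exact permutation p = 0.1). At equal depth, with each library thinned to 326501 reads, the numbers were 897 ± 10.5 and 905 ± 40.3 (exact permutation p = 0.8). The classes then differed in opposite directions: 608 ± 2.26 miRNAs were detected in input and 414 ± 0.245 in enriched libraries, against 203.2 ± 11.5 and 349 ± 33.4 snoRNAs and 79.5 ± 3.42 and 131 ± 8.36 snRNAs. The exact permutation p was 0.1 for each class.

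Most single RNAs differed between the groups. Of 953 tested RNAs, 846 changed, 347 of them upwards in the enriched libraries and the others downwards (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 783 changed at least 2-fold. The direction followed the class. Of 575 miRNAs, 44 rose and 465 fell, whereas 240 of 277 snoRNAs rose and 15 fell, and 60 of 94 snRNAs rose and 17 fell. Under total counts 82 miRNAs rose and 386 fell. Of 45 snRNAs tested with any 1 input library left out, 43 rose and 0 fell, and of 119 tested without enriched library 3, 42 rose and 24 fell. For 849 of the 953 RNAs (89.1%) the CPM ranges of the groups did not overlap, against 10% by chance. Log2 fold changes depend on the scaling. The median of all tested RNAs was -1.03 with TMM, -1.58 with DESeq2 size factors, -0.83 with upper-quartile factors and 0.04 with total counts, so an RNA at -1.03 on the TMM scale moved with the median RNA. Under all 4 scalings, 304 of the higher and 401 of the lower calls kept their direction and their side of the threshold. With 1 input library left out and all enriched libraries kept, between 542 and 558 RNAs changed, with 588 or 589 RNAs passing the low-count filter.

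**Figure D2:**
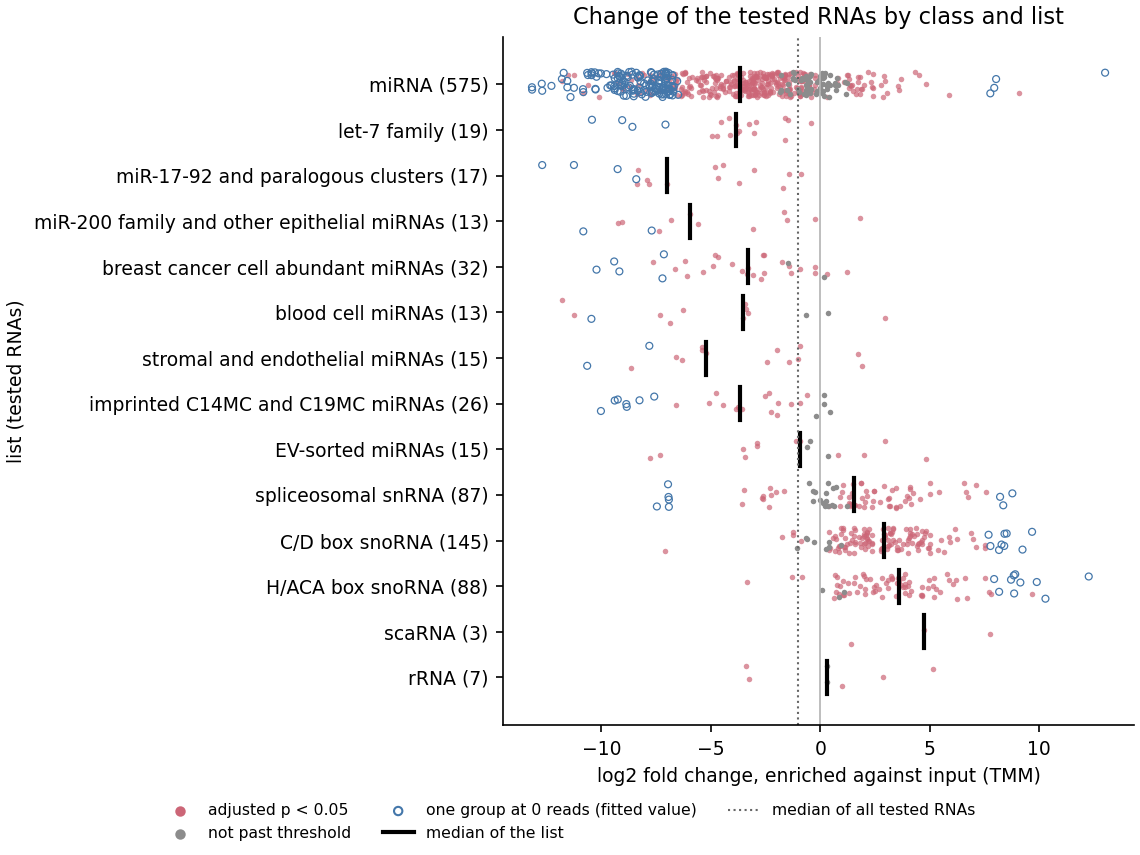
Log2 fold change of enriched against input (x axis, TMM scaling) for the tested RNAs of each class or list (y axis, number tested in brackets); each point is 1 RNA, red where its adjusted p is under 0.05, grey otherwise and open blue where 1 group had 0 reads and the plotted value depends on the fit. Black bars are list medians over the fitted values and the dotted line is the median of all tested RNAs, -1.03; the miRNA median lies at -3.69 and the C/D and H/ACA snoRNA medians at 2.90 and 3.58.

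H/ACA snoRNAs rose as a class. Of 88 tested members, 82 rose, 3 fell and 3 did not pass the test, with a median log2 fold change of 3.58 (camera adjusted p = 1.59e-17, and adjusted p = 0.0435 with an estimated correlation). SNORA67 (ENSG00000277985), in an intron of EIF4A1 on chromosome 17 (7577955 to 7578091), rose from 9.98 ± 1.91 to 745.8 ± 32.05 CPM (log2 fold change 6.22, SE 0.14, adjusted p = 3.40e-12). SNORA38B (ENSG00000200394), in an intron of NOL11 on chromosome 17 (67740669 to 67740799), had 13 reads over the input libraries and 1194 over the enriched ones, and rose from 0.826 ± 0.0766 to 701 ± 11.4 CPM (log2 fold change 9.65, SE 0.14, adjusted p = 1.12e-13). SNORA8, SNORA41, SNORA13 and SNORA5A, all in introns of other genes, had 0 reads in the input. On the TMM scale they were at least 1104-fold, 283-fold, 215-fold and 126.1-fold higher in the enriched libraries. All such bounds, here and below, change with the scaling. SNORA70B, SNORA70I and SNORA3C, singled out after their values were seen, fell; SNORA70B turned to a log2 fold change of 0.24 with total counts.

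C/D snoRNAs rose almost as widely, but the class call did not hold with an estimated correlation. Of the tested members, 132 rose, 5 fell and 8 did not pass the test, with a median of 2.90 (camera adjusted p = 5.21e-28, and adjusted p = 0.099 with an estimated correlation). The most abundant by CPM over all libraries, SNORD3A (ENSG00000263934, chromosome 17, 19188016 to 19188714), rose from 3715 ± 213 to 6090 ± 118 CPM (log2 fold change 0.71, SE 0.05, adjusted p = 1.02e-07), and its near-identical copy SNORD3B-2 rose by a log2 fold change of 0.67. SNORD114-9 and SNORD114-21, from the imprinted snoRNA cluster in introns of MEG8 on chromosome 14, had 0 input reads and were at least 190.7-fold and 138.4-fold higher. The enriched libraries had 12, 10 and 40 reads of SNORD114-9, and its fitted log2 fold change was 9.67, or 8.93 without enriched library 3. SNORD33, SNORD24, SNORD14B, SNORD97 and SNORD73A, singled out after their values were seen, fell. SNORD24 fell furthest, from 10026 to 8 reads (log2 fold change -7.08), and SNORD97 turned to 0.22 with total counts. All 3 tested scaRNAs, guides found in Cajal bodies, rose, from a log2 fold change of 1.40 for SCARNA10 to 7.76 for SCARNA12 (camera adjusted p = 0.0662, and adjusted p = 0.281 with an estimated correlation). Without input library 1 the value of SCARNA12 was 8.77.

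Of 87 tested RNAs in the spliceosomal snRNA list, 56 rose, 15 fell and 16 did not pass the test, with a median of 1.53 (camera adjusted p = 9.38e-07, and adjusted p = 0.181 with an estimated correlation). The list holds pseudogene copies and the histone-processing U7 RNA beside the spliceosomal genes. RNU2-2P (ENSG00000222328), which overlaps an exon of WDR74 on chromosome 11 (62841619 to 62841809), rose from 2955 ± 132 to 32175 ± 274 CPM (log2 fold change 3.44, SE 0.05, adjusted p = 2.23e-13), and the copy RNU2-36P on chromosome 9 rose by 3.11. These rows may hold many of the same reads, so RNU2-36P is not separate evidence of a rise. RNU4-78P and RNU1-44P, most changed in the list, had 0 input reads and 32 and 24 enriched reads, at least 98.4-fold and 73.8-fold higher. RN7SK (ENSG00000283293), the 7SK RNA that holds the elongation factor P-TEFb inactive, rose from 467 ± 22.4 to 3629 ± 101 CPM (log2 fold change 2.96, SE 0.05, adjusted p = 4.19e-13) and was the only member of its list.

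Of 7 tested rRNA rows, 3 rose, 2 fell and 2 did not pass the test, and the class median of 0.31 was not set apart from other RNAs (camera adjusted p = 0.278, and adjusted p = 0.553 with an estimated correlation). The 5.8S gene RNA5-8SN2 (ENSG00000276700), annotated on a scaffold outside the assembled chromosomes, rose from 150330 ± 7411 to 294380 ± 1710 CPM (log2 fold change 0.97, SE 0.08, adjusted p = 5.88e-07). Its value was 0.42 with DESeq2 size factors and 2.05 with total counts. RNA5S9, a 5S rRNA gene, rose by 2.85 and its pseudogene RNA5SP343 by 5.14, the latter from 3 to 14 reads. The 2 that fell, with -3.25 and -3.37, were annotated only as members of the 5.8S Rfam family. RNA5SP343 and these 2 were singled out after their values were seen.

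miRNAs fell as a class. The median of the 575 tested was -3.69, or -2.66 with the 147 that had 0 reads in 1 group set at the limit their floor allows (camera adjusted p = 3.43e-76, and adjusted p = 0.0435 with an estimated correlation). miR-21-5p, whose precursor lies in an intron of VMP1 on chromosome 17 (59841266 to 59841337), fell from 329000 ± 16018 to 27262 ± 308 CPM, a log2 fold change of -3.59 (SE 0.09, adjusted p = 6.89e-12). miR-7-5p, a brake on growth factor signalling, fell by 2.38 on the log2 scale (SE 0.06, adjusted p = 5.03e-12). miR-16-5p, which restrains the cell cycle, went from 1260045 to 39 reads and from 80324 ± 4272 to 22.2 ± 8.52 CPM (log2 fold change -11.78, SE 0.13, adjusted p = 3.53e-14). Its relatives miR-195-5p and miR-497-5p, from exons of MIR497HG on chromosome 17, had 6174 and 2279 input reads and 0 enriched reads, which puts miR-497-5p at least 82.3-fold lower. miR-3065-5p, miR-190a-5p and miR-19a-3p were also at 0 in the enriched group and, on the TMM scale, at least 224-fold, 164-fold and 162-fold lower. On that scale miR-190b-5p, miR-1277-5p, miR-219a-5p and miR-33a-5p, also at 0, were at least 121-fold, 86.85-fold, 73.3-fold and 73.2-fold lower.

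**Figure D3:**
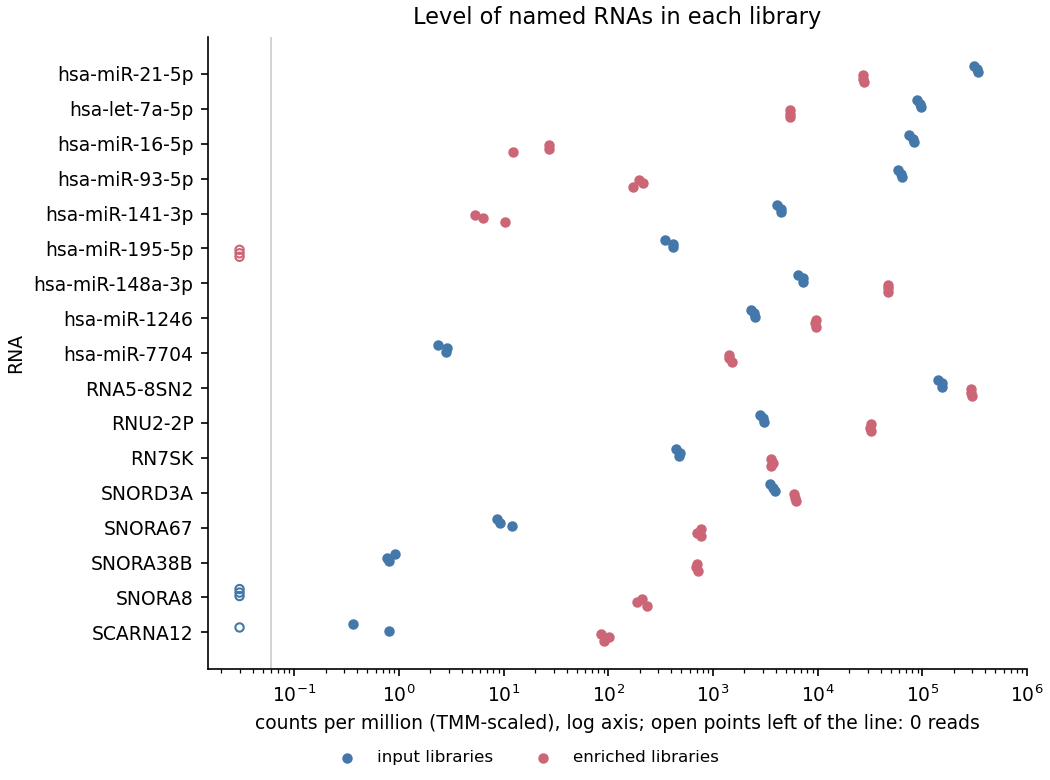
Level of 17 named RNAs in each library, in CPM on the TMM scale (x axis, log scale); filled points are libraries with reads, and open points left of the grey line libraries with 0 reads. In the enriched libraries miR-16-5p lies at 22.2 CPM on average against 80324 in the input, while RNU2-2P lies at 32175 against 2955.

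miRNA families fixed in advance fell with the class. Camera compared each list with all other tested RNAs, snoRNAs and snRNAs among them, so a low p may reflect the fall of miRNAs as a class. All 19 tested members of the let-7 family, which represses growth genes, fell, with a median of -3.83, or -3.69 with floors (camera adjusted p = 0.000159, and adjusted p = 0.33 with an estimated correlation). Log2 fold changes were -4.11 for let-7a-5p, -4.73 for let-7b-5p, -2.96 for let-7f-5p and -1.59 for let-7i-5p (adjusted p at most 2.47e-10); let-7d-3p, singled out after its value was seen, turned from -0.41 to 0.67 with total counts. All 17 tested members of the growth-promoting miR-17-92 cluster and its paralogues fell, with a median of -7.02, or -4.68 with floors (camera adjusted p = 0.000159, and adjusted p = 0.281 with an estimated correlation); miR-93-5p and miR-25-3p, both from an intron of MCM7, had -8.32 and -1.41. miR-106b-3p, singled out after its value was seen, turned from -0.88 to 0.21 with total counts. Of 13 miRNAs in the list of miR-200 family and other epithelial miRNAs, 12 fell and miR-200a-5p rose, with a median of -5.97, or -5.47 with floors (camera adjusted p = 0.00536, and adjusted p = 0.33 with an estimated correlation). miR-141-3p fell by 9.26 and miR-203a-3p by 5.60, and miR-375-3p, singled out after its value was seen, turned from -0.24 to 0.84 with total counts.

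Of 32 miRNAs listed as abundant in breast cancer cells, 28 fell, 2 rose and 2 did not pass the test, with a median of -3.31, or -2.89 with floors (camera adjusted p = 0.000169, and adjusted p = 0.33 with an estimated correlation). The 2 that rose, named after their values were seen, were miR-183-5p, with a log2 fold change of 0.31 that turned to -0.24 with DESeq2 size factors, and miR-27b-5p, which did not pass with DESeq2 size factors (adjusted p = 0.214). miR-182-5p, a neighbour of miR-183 in the same cluster, had -0.23 (SE 0.05, adjusted p = 0.000975), and its direction depended on the scaling, with 0.85 under total counts. Of the list of imprinted cluster miRNAs, 26 were tested, all from the chromosome 14 cluster and none from that of chromosome 19; 22 fell and 4 did not pass the test, with a median of -3.66, or -2.72 with floors (camera adjusted p = 0.00536, and adjusted p = 0.31 with an estimated correlation). In that list miR-411-5p had -4.75, or -5.62 without enriched library 3, and miR-127-3p had -0.94 with TMM and 0.14 with total counts. The call of the imprinted list was lost without input library 1 (adjusted p = 0.0655) or 3 (adjusted p = 0.0625).

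miRNAs in lists named for other cell types were present in the input, and most fell too. The lists are name patterns, so membership does not show the cell of origin. Of 13 blood cell miRNAs, 10 fell, miR-223-5p rose and 2 did not pass the test, with a median of -3.54 (camera adjusted p = 0.0262, and adjusted p = 0.31 with an estimated correlation). The most abundant and most changed member of this list was miR-16-5p (log2 fold change -11.78), also among the 10 RNAs with the highest CPM. miR-486-5p, abundant in red cells, went from 2047 ± 92.8 to 177 ± 19.6 CPM, and miR-142-3p, a leukocyte miRNA, from 24308 reads to 1 read, a ratio of 2634 with a counting interval of 473 to 104100; the 1 read came from enriched library 3. Of 15 stromal and endothelial miRNAs, 13 fell and miR-10b-5p and miR-100-5p rose, with a median of -5.20, or -2.45 with floors (camera adjusted p = 0.0197, and adjusted p = 0.33 with an estimated correlation); the endothelial miR-126-3p fell by 6.31. Of 8 liver and muscle miRNAs, 7 fell and 1 did not pass the test, with a median of -3.24, or -3.03 with floors (camera adjusted p = 0.028, and adjusted p = 0.24 with an estimated correlation). The liver miRNA miR-122-5p fell from 1266 ± 65.2 to 395 ± 17.4 CPM and the muscle miRNA miR-1-3p from 1878 ± 21.3 to 198 ± 8.82 CPM. Without enriched library 3, both the blood cell and the liver and muscle lists had an adjusted p of 0.0527. Of 7 neuronal miRNAs, 4 fell, miR-129-5p rose and 2 did not pass the test, with a median of -2.68 (camera adjusted p = 0.225, and adjusted p = 0.553 with an estimated correlation); miR-128-3p fell by 2.68 and miR-9-5p by 4.35. miR-223-5p, miR-10b-5p, miR-100-5p, miR-200a-5p and miR-129-5p were singled out after their values were seen.

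A smaller set of miRNAs rose. miR-148a-3p, with its precursor on chromosome 7 (25949919 to 25949986), rose from 6990 ± 420 to 47078 ± 240 CPM (log2 fold change 2.75, SE 0.06, adjusted p = 3.40e-12), and became the most abundant miRNA of the enriched libraries. miR-7704, which lies in an exon of HOXD1 on chromosome 2 (176188843 to 176188901), rose from 2.68 ± 0.27 to 1456 ± 57.0 CPM (log2 fold change 9.06, SE 0.10, adjusted p = 3.29e-14). miR-4791 had 0 input reads and 600 enriched reads and was at least 1845-fold higher on the TMM scale. Its precursor shares a stretch of at least 16 bases with the snoRNA gene SNORD20. Of 15 miRNAs often reported as high in EVs, 4 rose, 8 fell and 3 did not pass the test, with a median of -0.93 (camera adjusted p = 0.448, and adjusted p = 0.752 with an estimated correlation). miR-1246 rose from 2444 ± 101 to 9639 ± 97.8 CPM (log2 fold change 1.98, SE 0.05, adjusted p = 4.62e-12), while miR-320a-3p fell by 2.89. The precursor of miR-1246 shares at least 16 bases with 15 searched genes, among them the U2 gene RNU2-1. The others that rose, named after their values were seen, were miR-1290, miR-3960 and miR-223-5p, the last from 9 and 8 reads.

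Against other miRNAs alone, a test chosen after seeing the data, none of the 10 miRNA lists passed the threshold in camera. The let-7, miR-17-92 and EV lists came closest (adjusted p = 0.061 each), the first pair towards a larger fall and the EV list towards a smaller one, and these 3 had an unadjusted p under 0.05. With an estimated correlation the smallest adjusted p was 0.964. For all lists, the counts of members that rose and fell were the same when adjusted over the list alone. Fry called 16 of 16 lists in the directional test, with the largest adjusted p of 0.00266 for rRNA.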

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

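Alternatives chosen only after seeing the data were those that leave out the 36 rows or the replicate 3 libraries, thin the libraries before the edgeR and list tests, keep rows with the same counts once, test miRNA lists against other miRNAs, flip signs within pairs, or leave out miR-21-5p. With each library left out in turn, between 542 and 871 RNAs changed, between 256 and 575 fell and between 504 and 828 changed at least 2-fold. The low counts came without an input library and have a known source: the low-count filter follows the median library size and passed 588 or 589 RNAs then, against 1104 to 1121 without an enriched library. Over all alternatives, 29 to 82 miRNAs rose and 204 to 634 fell, 173 to 310 snoRNAs rose and 3 to 24 fell, and 29 to 87 snRNAs rose and 0 to 32 fell, with different numbers tested. Thinned to one depth, 472 RNAs were tested, 447 changed, 209 fell and 417 changed at least 2-fold. The share of calls that were higher was 41.0%, with 35.98% under DESeq2 size factors, 42.8% under upper-quartile factors and 50.5% under total counts. With the replicate number as a block, 856 RNAs changed (351 higher, 505 lower) and 790 at least 2-fold, and it changed no other call of a named RNA or a list. Sign flips within these pairs gave an exact p of 0.25, the smallest possible, for each class share and for the number of detected RNAs. The DESeq2 Wald test called 991 of 1397 RNAs, 371 higher and 620 lower. Without the 36 rows 846 of 940 RNAs changed, and without replicate 3 libraries 793. The median log2 fold change of the tested RNAs was then -1.521 and -1.682, against -1.03 in the main fit. The size of log2 fold changes thus also depends on these rows and libraries. Lists past the threshold numbered 12, and 2 with an estimated correlation; the cause was not tested. The scaRNA list passed in 5 alternatives (adjusted p from 0.0298 to 0.0499). Imprinted miRNAs lost the call after thinning (adjusted p = 0.15), and liver and muscle miRNAs with the stricter filter (0.0569) or without replicate 3 libraries (0.0634). Of the comparisons of a named RNA under an alternative, 1140 kept direction and side of the threshold. The exceptions were miR-182-5p, which turned to 0.8494 under total counts, 0.03072 under the stricter filter and 0.3536 after thinning, and lost its call under upper-quartile factors and without input library 1, input library 3 or enriched library 1 (adjusted p from 0.0607 to 0.276), and miR-127-3p, which turned to 0.1378 under total counts. The number of RNAs detected per library differed by -424.7, enriched minus input, but by 8.842 after thinning and by 71.58 after thinning with at least 10 reads, so depth set the unthinned difference; thinning was planned for this count. Depth also limits the enriched group, where 0 reads exclude only an RNA above 3 reads over 3 libraries.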

Other observations

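Tests chosen after the result was seen were those on the 36 rows, on the depth and scaling behind the higher miRNAs, on H/ACA against C/D snoRNAs, on miR-1246, on GC content and on the miR-15/16 family, and the set of genes searched for shared sequence was reworded to match the search after its value was known; RNAs named in the paragraphs below were singled out after their values were seen.

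The rise of snoRNAs was uneven. SNORD1B went from 926 to 12451 reads (log2 fold change 6.96, edgeR adjusted p = 9.37e-15) and became the snoRNA with the most enriched reads, ahead of SNORD3A. SNORD43 and SNORD58C rose by 6.16 and 6.22, while SNORD33, which was the most abundant snoRNA of the input outside the SNORD3 copies with 28812 reads, fell to 924 reads (-1.76). Minor spliceosome RNAs differed as well: U11 (RNU11) rose by 3.19 and U12 (RNU12) by 0.88. The U7 RNA gene RNU7-1, which acts in histone mRNA processing, rose by 1.43. Of 416 rows with at least 30 enriched reads, 14 had 0 input reads (12 snoRNAs, 1 snRNA and 1 miRNA) and 5 had 1 to 9, although input libraries were deeper.

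In the miR-15/16 family, whose members share a seed sequence, miR-15a-5p went from 12966 to 2 reads, miR-15b-5p from 20113 to 30 and miR-424-5p from 5162 to 1. The family was picked because miR-16-5p, miR-195-5p and miR-497-5p were among the 10 largest falls, so those 3 were kept out of its test. The median of the other 3 differed by -4.954 from that of 328 other miRNAs with at least 100 input reads per library (permutation p = 0.066). It rests on the single enriched read of miR-424-5p, which leaves open whether the family fell further. Across the 298 miRNAs with a precursor sequence among 334 with a mean of at least 100 input reads, log2 fold change rose with the GC content of the precursor (Spearman rho 0.2165, bootstrap 95% interval 0.101 to 0.322, Pearson r 0.211, permutation p = 0.00012). This is a correlation across RNAs, which are not independent replicates. The 75 with the lowest GC content had a median of -5.30 and the 75 with the highest -3.09. A sequence-dependent recovery or capture may contribute, and the mature sequences were not used here.

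In 36 Ensembl rows both replicate 3 libraries had 0 reads, with 0 such rows for replicate 1 and 2 for replicate 2, and 0.266 expected by chance. Low counts do not account for them, since 32 of the rows had over 10 expected reads over the replicate 3 libraries, and the highest expectation was 648. Of the 36, 94.44% were named only by an Rfam family, against 11.2% of 420 other Ensembl rows (Fisher's exact p = 1.56e-26). A candidate explanation is that replicate 3 was counted against another annotation than replicates 1 and 2, and no biological explanation was tested.

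miRNAs that rose stand against the fall of their class. Of 44, 42 had a precursor sequence, and 11.9% of these shared 16 bases with a gene of the searched set (exact 95% interval 3.98 to 25.6). Among those that fell, 4.57% did (Fisher's exact p = 0.058). The set held snRNA, snoRNA, 5S, 5.8S, Y, vault, 7SK, 7SL and other miscellaneous RNA genes and mitochondrial tRNA and rRNA genes. Shared stretches of this length were thus not found for most of the miRNAs that rose. Shorter or imperfect matches were not searched, so reads of these genes counted as miRNAs are not excluded. Low counts and scaling do not account for all of the miRNAs that rose, since 9 had at least 100 reads per library in both groups and 33 rose under each of the 4 scalings. Fragments of 18S, 28S or cytosolic tRNA, which were not searched, may still lie behind some, and so may carriage of the label. The miR-1246 precursor shares at least 16 bases with 15 searched genes, among them RNU2-1, RNU2-26P (log2 fold change 5.01, edgeR adjusted p = 8.78e-07) and RNU2-29P (0.61, adjusted p = 0.18), at most 19 bases (RNU2-7P, not itself tested) and 14 with RNU2-2P, so U2 fragments counted as miR-1246 may contribute.

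The opposite movement of snRNAs and snoRNAs against miRNAs was also seen at equal depth, where 98.54% of the snRNA and snoRNA calls were higher. With copies and Rfam-named rows left out, 96.17% of these calls were higher (226 higher and 9 lower of 248 tested). At equal depth, 50.3 snoRNAs and 14.8 snRNAs on average had at least 10 reads in an input library, against 200.6 and 36.1 in an enriched library. The low-count filter thus admitted many of them through the enriched group, which favours higher calls. The 98.54% therefore cannot exclude an effect of depth. Within these classes the change did not grow with annotated gene length (Spearman rho -0.0213 over 371 genes, bootstrap 95% interval -0.118 to 0.0794). It did among the 87 RNU-named genes (rho 0.333, adjusted permutation p = 0.0074). Many of the 87 are copies of the same snRNA families and may share reads, so they are not independent. That trend cannot be told apart from differences between families. The length of the sequenced fragments was not used, so neither result bears on recovery by fragment length. The length test covers snRNA and snoRNA genes only, so a size difference between miRNAs and the longer classes may still contribute, and so may background binding or glycan labelling, which were not tested without a recovery from unlabelled EVs.

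10 splits of the 6 libraries are too few for a share under 0.05. 1 of the 10, the real one, gave as many changed RNAs (846, and 783 at least 2-fold), and the highest of the others was 0 for both. Every other split holds input and enriched libraries in both of its groups. The difference between input and enriched then becomes spread within the groups, so these 0 counts carry little information. The 3 other splits that part every same-numbered pair gave 0 changed RNAs and 12 or 13 lists past the threshold, and the 6 that keep 2 pairs together gave 0 and 10 to 13. For lists 8 of the 10 splits gave as many as the real 12, and the highest other gave 13, so with its preset correlation camera called lists in splits that mix the groups unevenly. H/ACA snoRNAs had a median log2 fold change 0.68 above C/D snoRNAs (bootstrap 95% interval -0.0765 to 1.501, permutation p = 0.06), too wide to tell the classes apart. Of 71 hairpins with both arms at 100 or more input reads per library, the arm with fewer input reads had the larger log2 fold change in 33 (two-sided exact binomial p = 0.635), so no preference for the minor arm was seen.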
